A study of Mus musculus with 24 samples.

How the data were processed

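The samples were 24 pools of lung RNA, each from 2 mice, measured on 12 two-colour microarrays with 62976 spots on 3 slides, each dye of an array holding its own sample. Per the labels, the groups were Ctrl, rCNT, tCNT, SES, BayTubes, Graphite and fullerene, with 3, 3, 3, 3, 4, 4 and 4 samples. The deposited values are log2 signals, 1 per spot and sample. The authors list Agilent Feature Extraction and limma in their processing notes, without versions or settings. The sorted values of any pair of samples differed by at most 0.086, as they do after quantile normalization across samples. Array signals carry no counts, so the number of samples limits the precision.

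Of the spots, 31465 had a gene name in the platform table and 31511 did not. Names were brought up to date with a reference table of assembly GRCm38.p6, which matched 29050 spots by accession, 2061 by symbol and 349 by synonym, while 5 kept the platform symbol. A gene needed a signal above the 40th percentile in at least 3 samples and was represented by its spot with the highest mean, which left 16530 of 20738 genes. Where another bright spot of the same gene could be compared, its change had the same sign in 91.2% of 511 spots whose gene changed by over 1 log2 unit after rCNT.

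Changes were estimated with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a term for group and dye, array as a random block (correlation 0.399), moderated variances (16 residual and 3.54 prior degrees of freedom) and Benjamini-Hochberg adjustment over genes within a comparison. Tests were 2-sided, and an adjusted p under 0.05 counted as a change. Each material was compared with Ctrl and with the mean of the other 5, rCNT was compared with tCNT, and an F test asked for any difference among the 6 materials. Of 42 gene and marker lists, 41 with at least 4 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way on balance. Adjusted p of lists are over the lists of a comparison.

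The groups, comparisons, lists, naming rule and alternatives were set before the data were examined, except where stated. By that rule, the genes that could be named were the 8 highest and 8 lowest past the threshold, the 2 members of each list with the smallest p where they passed, and the 5 genes with the smallest p where fewer than 5 passed. The genes named are a selection from these, made after their values were seen, except that Scgb1a1 and Myh6 after tCNT and Saa3 in fullerene 21 were named outside the rule to describe a list or a sample. Alternatives changed the dye term, the array block, the filter, the normalization, the spot of a gene, the variance prior, the threshold, the samples in the fit, the slide and the list test, and left out each sample in turn. Leaving out the array of rCNT 4 and Graphite 16 was added after seeing the data. Fits within a slide used the array correlation of the full fit, and a group with 1 sample there was assumed to vary like the others.

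The fit was tested on simulated data, drawn as normal noise with the fitted variances and array correlation, with 200 genes changed. For rCNT against Ctrl it found 32, 80 and 98% of genes changed 1.5-fold, 2-fold and 4-fold, with 3.12% of calls among unchanged genes, and for fullerene against Ctrl 60, 92 and 100%, with 5.88%. For SES against Ctrl with no simulated change it made 0 calls. Spots without a gene name were left out of the comparisons and tested apart.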

Results

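Lung RNA of female C57BL/6 mice aged 7 to 8 weeks was measured on 2-dye expression arrays after repeated dosing with 1 of 6 carbon nanomaterials. The labels name the materials rCNT, tCNT, SES, BayTubes, Graphite and fullerene, of which rCNT, tCNT and BayTubes are carbon nanotubes. The labels do not give the meaning of SES, so whether it is a nanotube too is left open. Each was given at 10 µg a day in 50 µl by oropharyngeal aspiration, in which a droplet at the back of the throat is breathed in, for 4 days, and lungs were taken 24 h after the last dose. Control mice (Ctrl) received saline (PBS) by the same route. RNA of 2 mice was pooled per sample, which gave 24 samples: 3 each of Ctrl, rCNT, tCNT and SES and 4 each of BayTubes, Graphite and fullerene. Array signals have no count depth, so the number of samples limits the precision. The median standard error of a log2 change against Ctrl lay between 0.13 and 0.16.

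Samples that shared an array resembled each other beyond their groups. The median correlation of their residuals was 0.411 over the 12 arrays, from 0.175 to 0.827, against -0.053 over the 264 other pairs of samples. The residual SD was 0.469 in rCNT 4, 0.414 in Graphite 13 and 0.387 in Graphite 16, and rCNT 4 and Graphite 16 shared the array with the correlation of 0.827. Graphite 13 held 4868 distinct values, against 7864 to 12122 in the other samples. Ctrl samples were present on 2 of the 3 slides.

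The comparisons against Ctrl ask which lung genes each material changed, and the series title asks how far these gene sets are distinct or overlap. At an adjusted p under 0.05 (limma), 3598 of 16530 genes changed after rCNT, 526 after BayTubes, 187 after Graphite, 117 after tCNT and 43 after fullerene. After SES the limma count was 0, with 747 genes at an unadjusted p under 0.05. That is fewer than unchanged genes alone would be expected to give. All groups shared 1 estimate of the spread per gene. The residual SD was 0.154 to 0.208 in the SES samples, against 0.244 to 0.469 in the rCNT samples. The test for SES may thus be too strict, and its low count does not show that SES changed nothing. The numbers of genes higher and lower were 2044 and 1554 after rCNT, 357 and 169 after BayTubes, 90 and 97 after Graphite, 113 and 4 after tCNT and 25 and 18 after fullerene. A change of at least 1.5-fold was kept by 2145, 327, 127, 111 and 38 of these genes in the same order.

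**Figure D1:**
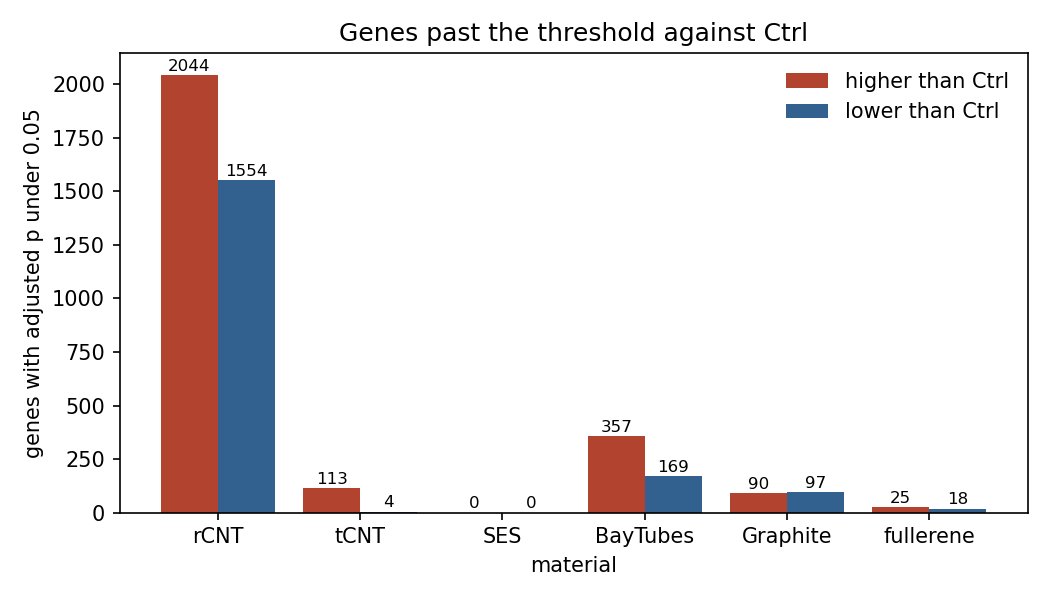
Genes past an adjusted p of 0.05 in each material against Ctrl, split into higher and lower (vertical axis: number of genes; horizontal axis: material). The bars for rCNT reach 2044 and 1554, and SES has 0 genes in both directions.

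After rCNT, genes that attract immune cells rose by large factors. The chemokine Ccl24, which attracts eosinophils, rose by 6.15 ± 0.49 on the log2 scale (SE, n = 3 samples against 3), a 70.9-fold change. The monocyte-attracting chemokines Ccl8, Ccl7 and Ccl2 rose by 5.13 ± 0.46, 4.99 ± 0.33 and 4.90 ± 0.38, and Cxcl5, which attracts neutrophils, by 5.03 ± 0.36. Cxcl5 was at 5.70 in Ctrl, where the 40th percentile of the samples lay (5.69 to 5.75), so the size of its change is uncertain. Among the neutrophil and monocyte chemokines and cytokines, 15 of 16 (15 adjusted over the list alone) rose (median 2.84, adjusted p = 2.01e-36). Genes of type 2 inflammation, the allergy-like arm of immunity, rose in 23 of 27 (23 adjusted over the list alone; median 2.45, adjusted p = 3.33e-38). These included Clca1 (6.96 ± 1.11) and Slc26a4 (5.56 ± 0.44) of mucus-making airway cells, Arg1 (4.54 ± 0.50), Retnlb (4.37 ± 0.33) and the chemokine Ccl17 (4.08 ± 0.30). Retnlb was at 5.31 in Ctrl, below the 40th percentile of every sample (5.69 to 5.75), so the size of its change is uncertain. Acute phase genes rose in 13 of 14 (13 adjusted over the list alone), with Saa3 at 5.89 ± 0.60 and Saa1 at 4.37 ± 0.40 (median 1.67, adjusted p = 2.03e-18).

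Cell cycle genes rose after rCNT in 24 of 25 (24 adjusted over the list alone), with the mitotic kinase Cdk1 at 2.60 ± 0.29 and the ubiquitin ligase partner Ube2c at 2.72 ± 0.31 (median 2.21, adjusted p = 8.71e-34). Interferon-induced genes rose in 15 of 22 (15 adjusted over the list alone), with Rsad2 at 2.04 ± 0.22 and Mx2 at 1.33 ± 0.15 (median 1.00, adjusted p = 1.44e-12, or 0.0669 with an estimated correlation). Markers of monocytes and recruited macrophages were higher in 10 of 13 (10 adjusted over the list alone), with the macrophage elastase Mmp12 at 3.01 ± 0.45 (median 1.63, adjusted p = 3.18e-08, or 0.057 with an estimated correlation). Markers of eosinophils and basophils were higher in 4 of 7 (5 adjusted over the list alone), with the granule protein gene Prg2 at 2.89 ± 0.33 (median 0.67, adjusted p = 0.000354, or 0.102 with an estimated correlation). Prg2 was at 5.45 in Ctrl, below the 40th percentile of every sample (5.69 to 5.75), so the size of its change is uncertain. Dendritic cell markers were higher in 6 of 12 (6 adjusted over the list alone; median 0.51, adjusted p = 0.000336). Genes of antigen presentation by MHC class II were higher in 4 of 10 (5 adjusted over the list alone), among them Cd74 at 0.79 ± 0.18 (median 0.50, adjusted p = 0.0162, or 0.326 with an estimated correlation). The matrix and fibrosis list rose in 7 of 21 (10 adjusted over the list alone), with the protease inhibitor Timp1 at 3.70 ± 0.46 (median 0.50, adjusted p = 0.00106, or 0.245 with an estimated correlation). The complement list rose in 7 of 15 (7 adjusted over the list alone), with Cfb at 1.85 ± 0.29 (median 0.35, adjusted p = 0.000651, or 0.17 with an estimated correlation). Inflammasome and lysosomal genes rose in 9 of 19 (10 adjusted over the list alone), with the lysosomal protease Ctsk at 1.98 ± 0.30 (median 0.63, adjusted p = 0.00415, or 0.245 with an estimated correlation). Metallothioneins and genes of metal response rose in 5 of 11 (5 adjusted over the list alone), with Mt2 at 2.17 ± 0.38 (median 0.28, adjusted p = 0.00904, or 0.182 with an estimated correlation).

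Several genes of the resting lung fell after rCNT. Endothelial markers were lower in 8 of 12 (8 adjusted over the list alone), with the growth factor receptor Kdr at -0.76 ± 0.15 and Ramp2 at -0.80 ± 0.15 (median -0.68, adjusted p = 1.85e-05, or 0.0795 with an estimated correlation). Alveolar type 1 cell markers were lower in 6 of 10 (9 adjusted over the list alone), with Emp2 at -0.91 ± 0.18 (median -0.71, adjusted p = 0.000354, or 0.102 with an estimated correlation). Single genes that fell included the club cell enzyme Cyp2f2 at -1.27 ± 0.18, the methyltransferase Inmt at -1.17 ± 0.21, the surfactant lipid transporter Abca3 at -0.55 ± 0.13 and the fibroblast receptor Pdgfra at -0.95 ± 0.19. The glutathione transferases Gstm1 and Gsta3 fell by 1.40 ± 0.19 and 1.48 ± 0.24, the fatty acid binding protein Fabp1 by 2.21 ± 0.27, the lipid droplet gene Cidec by 1.59 ± 0.17 and the esterase Pon1 by 2.46 ± 0.24. Txnip was lower at -2.08 ± 0.58 and Selenbp1 at -2.35 ± 0.57, with SDs of 1.85 and 1.64 among the rCNT samples, and without the array of rCNT 4 and Graphite 16, an alternative chosen after seeing the data, they were at -1.38 and -1.79. Of the clock genes, 5 of 15 fell (7 adjusted over the list alone), with Per1 at -1.04 ± 0.16 and Tef at -1.12 ± 0.21 (median -0.42, adjusted p = 0.00568). Ciliated cell markers were higher in 7 of 13 (7 adjusted over the list alone), with Foxj1, the regulator of motile cilia, at 1.10 ± 0.20 and Tekt1 at 0.76 ± 0.14 (median 0.47, adjusted p = 0.0216, or 0.245 with an estimated correlation), and Foxp3 of regulatory T cells was higher by 0.97 ± 0.22. Markers of mesothelium had a median of -0.46 (adjusted p = 0.0323, or 0.286 with an estimated correlation). Those of red blood cells had a median of -0.68 (adjusted p = 0.032, or 0.304 with an estimated correlation). Markers of smooth muscle and pericytes had a median of 0.39 (adjusted p = 0.0424, or 0.375 with an estimated correlation). Those of skeletal muscle had a median of 0.31 (adjusted p = 0.032, or 0.245 with an estimated correlation).

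The 42 genes named here for rCNT had adjusted p from 6.3e-08 to 0.014. Of these genes, 40 stayed past the threshold whichever sample of rCNT or Ctrl was left out, and the exceptions were Txnip (-1.45 without rCNT 4 and -1.96 without Ctrl 2) and Cd74 (0.487 without rCNT 5). Within slide 1 (1 sample against 1), 99.1% of the 3598 genes had the same direction, and within slide 2 (1 against 2) 87.7%, where Ramp2 (0.0791), Abca3 (0.0791) and the median of the red blood cell markers (0.467) had the opposite sign. In this and the later comparisons the genes were called on samples that include those of the slide, so a shared direction is no separate evidence. The count was 1074 with array as a fixed term and 1009 when the other groups were left out of the fit. Of the 21 lists called, 6 held with an estimated correlation, and fry called all 21.

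**Figure D2:**
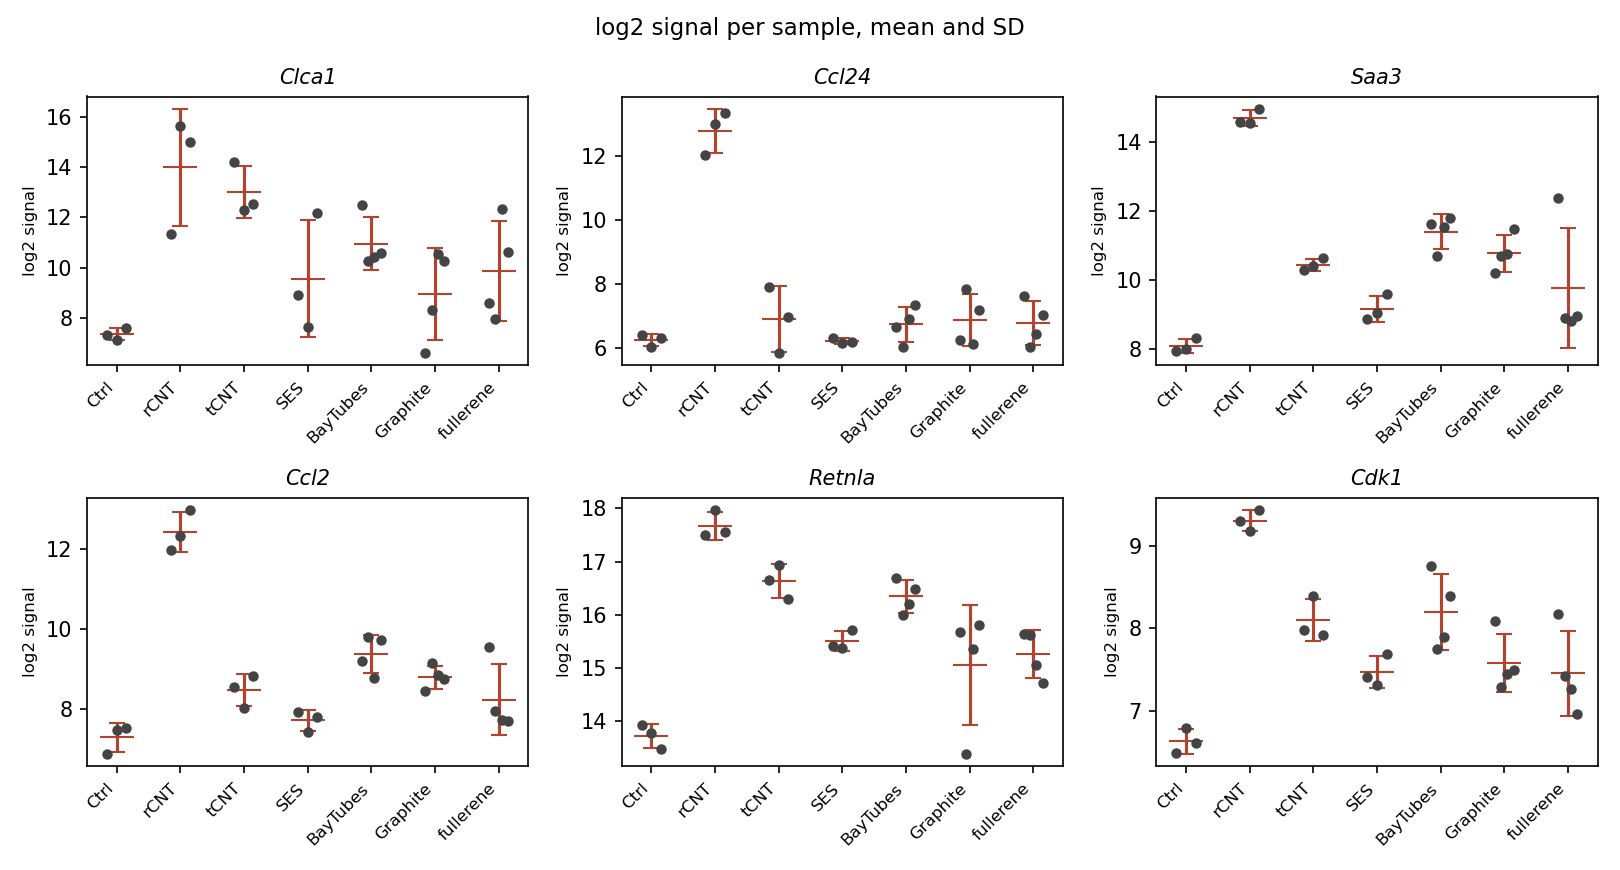
Log2 signal of inflammation genes in each sample (vertical axes: log2 signal; horizontal axes: group). Points are samples and bars are group means with SD. The Ccl24 mean is 12.80 in rCNT and 6.25 in Ctrl.

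After tCNT, Clca1 rose by 5.83 ± 1.09 (SE, n = 3 against 3), the anion exchanger Slc26a4 by 2.47 ± 0.44, the mucin chaperone Agr2 by 2.48 ± 0.35, Tff2 by 2.25 ± 0.43 and the airway mucin Muc5b by 2.01 ± 0.39. The macrophage and airway gene Retnla rose by 2.92 ± 0.42, the iron-binding protein Ltf by 2.62 ± 0.57 and the chemokine Ccl8 by 1.98 ± 0.45. Type 2 inflammation genes rose in 6 of 27 (12 adjusted over the list alone; median 0.66, adjusted p = 2.21e-15). Club and secretory cell markers rose in 2 of 10 (5 adjusted over the list alone; median 0.85, adjusted p = 5.15e-05). In the club and secretory list Muc5b and Ltf passed, while Scgb1a1, the main club cell product, was at -0.11 ± 0.11. Cell cycle genes rose in 7 of 25 (22 adjusted over the list alone), with Cdk1 at 1.45 ± 0.29 and Cdc20 at 1.42 ± 0.30 (median 1.20, adjusted p = 1.79e-34). Ciliated cell markers rose in 2 of 13 (8 adjusted over the list alone), with Rsph1 at 0.80 ± 0.17 and Tekt1 at 0.66 ± 0.14 (median 0.53, adjusted p = 4.04e-09).

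Acute phase genes rose after tCNT in 1 of 14 (3 adjusted over the list alone), with the fibrinogen chain Fgg at 1.19 ± 0.22 (median 0.45, adjusted p = 4.03e-07). The lysosomal protease Ctsk rose by 1.65 ± 0.29 in a list of inflammasome and lysosomal genes with a median of 0.21 (adjusted p = 0.00139, or 0.193 with an estimated correlation). Fkbp5, which glucocorticoids induce, rose by 0.98 ± 0.16. The 4 genes that fell were the ceramidase Acer2 (-0.94 ± 0.21), Per1 (-0.90 ± 0.16), Upk1a (-0.66 ± 0.15) and Cyp2d12 (-0.61 ± 0.14). Heart muscle markers had a median of 1.27 (adjusted p = 1.6e-09, or 0.138 with an estimated correlation). None of these 12 heart genes passed over all genes and 9 passed adjusted over the list alone, with Myh6, the heart myosin, at 1.74 ± 0.72. The mean score of the heart list was 1.10 ± 0.26 (SD, n = 3) in tCNT and 0.00 ± 0.80 (SD, n = 3) in Ctrl. The neutrophil and monocyte chemokines and cytokines had a median of 0.63 (adjusted p = 2.39e-09, or 0.0555 with an estimated correlation). Alveolar macrophage markers had a median of 0.44 (adjusted p = 0.00249, or 0.0555 with an estimated correlation). Markers of monocytes and recruited macrophages had a median of 0.31 (adjusted p = 0.00859, or 0.477 with an estimated correlation). T cell markers had a median of 0.20 (adjusted p = 0.0116, or 0.381 with an estimated correlation). Metal response genes had a median of 0.26 (adjusted p = 0.00411, or 0.166 with an estimated correlation). Endothelial markers had a median of -0.27 (adjusted p = 0.000514, or 0.193 with an estimated correlation). Alveolar type 1 cell markers had a median of -0.24 (adjusted p = 0.00361, or 0.193 with an estimated correlation).

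The 19 genes named for tCNT had adjusted p from 0.0024 to 0.048. The count of 117 genes became 0 without tCNT 8, 14 without tCNT 9, 327 without tCNT 7, 24 without Ctrl 1, 13 without Ctrl 2 and 32 without Ctrl 3. The genes still past the threshold among the 19 were 0, 4, 19, 5, 4 and 6 in that order. The gene count was 0 with array as a fixed term and 51 with the other groups left out of the fit. Within slide 1 (2 samples against 1), all of the 117 genes (100%) had the same direction, and slide 2 held no tCNT sample. Of the 14 lists called, 5 held with an estimated correlation and 6 by fry.

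After SES no single gene passed the threshold in limma, with 747 at an unadjusted p under 0.05. This is fewer than unchanged genes alone would be expected to give. With a spread estimate shared by all groups, it does not show that SES changed nothing. The 5 genes with the smallest p were lower: Kri1 at -1.23 ± 0.22 (SE, n = 3 against 3), Kmt5c, a histone methyltransferase, at -1.14 ± 0.20, Pex10 at -0.83 ± 0.15, U2af2, a splicing factor, at -0.81 ± 0.16 and Ykt6 at -0.76 ± 0.12, with adjusted p from 0.071 to 0.14. Cell cycle genes were higher as a list (median 0.63, adjusted p = 6.5e-17, or 0.478 with an estimated correlation), as were the neutrophil and monocyte chemokines and cytokines (median 0.49, adjusted p = 3.43e-06, or 0.478 with an estimated correlation). Interferon-induced genes had a median of 0.37 (adjusted p = 4.44e-06, or 0.512 with an estimated correlation). Natural killer cell markers had a median of 0.43 (adjusted p = 8.19e-05, or 0.478 with an estimated correlation). Type 2 inflammation genes had a median of 0.18 (adjusted p = 0.000131, or 0.512 with an estimated correlation). Acute phase genes had a median of 0.23 (adjusted p = 0.011, or 0.512 with an estimated correlation). Inflammasome and lysosomal genes had a median of 0.14 (adjusted p = 0.0194, or 0.513 with an estimated correlation). In these 7 lists 0 genes passed over all genes, and adjusted over the list alone 2 passed in the chemokine list, 2 in the type 2 list and 1 in the inflammasome list. With an estimated correlation and by fry 0 of the 41 lists passed for SES, and 13 passed by camera without SES 10 and 11 without SES 11. The gene count was 2 with the other groups left out of the fit and 8 within slide 2.

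After BayTubes, inflammation and cell cycle genes rose and 1 clock gene fell strongly. Saa3 rose by 3.13 ± 0.50 (SE, n = 4 against 3), Saa1 by 1.63 ± 0.33, Ccl2 by 2.07 ± 0.31, Ccl8 by 2.03 ± 0.37 and Ccl12 by 1.36 ± 0.25. The neutrophil and monocyte chemokines and cytokines rose in 8 of 16 (10 adjusted over the list alone; median 0.84, adjusted p = 9.77e-16). Acute phase genes rose in 4 of 14 (8 adjusted over the list alone; median 0.51, adjusted p = 1.3e-09). Cell cycle genes rose in 21 of 25 (23 adjusted over the list alone), with Cdc20 at 1.58 ± 0.25 and Cdk1 at 1.54 ± 0.24 (median 1.24, adjusted p = 3.65e-40). Type 2 inflammation genes rose in 6 of 27 (11 adjusted over the list alone), with Retnla at 2.63 ± 0.35, Slc26a4 at 2.29 ± 0.36, Agr2 at 1.94 ± 0.29 and Ccl17 at 1.09 ± 0.24 among the genes raised (median 0.46, adjusted p = 3.54e-11, or 0.0554 with an estimated correlation). The eosinophil-type ribonuclease Ear6, of the markers of eosinophils and basophils, rose by 1.20 ± 0.17.

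Arntl (Bmal1), the core activator of the circadian clock, fell after BayTubes by 2.19 ± 0.18, while the clock repressor Per2 rose by 1.43 ± 0.19. Of the clock genes, 6 of 15 (8 adjusted over the list alone) rose and 1 fell (median 0.44, adjusted p = 0.00334). Spon2 fell by 1.81 ± 0.14, the aldehyde dehydrogenase Aldh2 by 1.14 ± 0.20, Pon1 by 1.12 ± 0.20 and Col13a1 by 0.88 ± 0.17. The retinoic acid hydroxylase Cyp26b1 fell by 2.43 ± 0.60, with an SD of 1.97 among the Ctrl samples. For Cyp26b1, 3 of 4 BayTubes samples lay below every Ctrl sample, and the call was lost in some fits with 1 sample left out. Ctsk rose by 1.77 ± 0.24 and Timp1 by 1.46 ± 0.38, and the glucocorticoid-induced genes Fkbp5 and Zbtb16 rose by 1.12 ± 0.13 and 1.30 ± 0.26. Ciliated cell markers rose in 4 of 13 (7 adjusted over the list alone), with Rsph1 at 0.65 ± 0.14 and Tekt1 at 0.57 ± 0.12 (median 0.36, adjusted p = 0.000102, or 0.0554 with an estimated correlation). Fibroblast markers were lower, with Dpt at -0.59 ± 0.14 (median -0.26, adjusted p = 0.0245, or 0.0659 with an estimated correlation), as were endothelial markers, with the tight junction gene Cldn5 at -0.87 ± 0.19 (median -0.27, adjusted p = 0.00106, or 0.23 with an estimated correlation). Fat markers were lower, with Cidec at -0.68 ± 0.14 (median -0.37, adjusted p = 0.00803, or 0.338 with an estimated correlation). Inflammasome and lysosomal genes had a median of 0.25 (adjusted p = 0.000159, or 0.14 with an estimated correlation). Alveolar macrophage markers had a median of 0.43 (adjusted p = 0.0245, or 0.198 with an estimated correlation). Metal response genes had a median of 0.20 (adjusted p = 0.0188, or 0.261 with an estimated correlation). Markers of monocytes and recruited macrophages had a median of 0.46 (adjusted p = 0.018, or 0.463 with an estimated correlation). Alveolar type 1 cell markers had a median of -0.25 (adjusted p = 0.0308, or 0.409 with an estimated correlation). Red blood cell markers had a median of -0.38 (adjusted p = 0.0197, or 0.34 with an estimated correlation).

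Adjusted p of the 28 genes named for BayTubes ran from 9.0e-07 to 0.037. The count of 526 genes became 320 without BayTubes 17, 254 without BayTubes 20, 241 without Ctrl 2 and 247 without Ctrl 3. Of the 28 named genes, 17 passed whichever sample was left out. The gene count was 240 with no array block, 61 with array as a fixed term and 79 with the other groups left out of the fit. Within slide 1 (3 samples against 1), 100% of the 526 genes had the same direction, and within slide 2 (1 against 2) 90.7%, where Rsph1 (-0.0892) and Dpt (0.0487) had the opposite sign, as had the medians of alveolar macrophage (-0.0948), alveolar type 1 (0.3), endothelial (0.134) and red blood cell (0.599) markers. Of the 15 lists called, 4 held with an estimated correlation and 10 by fry.

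After Graphite, Saa3 rose by 2.5 ± 0.53 (SE, n = 4 against 3), Ccl8 by 1.72 ± 0.40 and Ccl2 by 1.55 ± 0.34. The cell cycle genes Cenpe and E2f8 rose by 1.11 ± 0.26 and 1.07 ± 0.26, and the natural killer cell receptor Klrb1c by 0.84 ± 0.18. The clock genes Nr1d2 and Arntl moved apart, Nr1d2 at 0.94 ± 0.14 and Arntl at -1.0 ± 0.19. Among the genes that fell were Nxph3 (-1.74 ± 0.39), the kinase Hipk2 (-1.55 ± 0.26), Aldh2 (-1.37 ± 0.22), Kri1 (-1.17 ± 0.20) and the matrix gene Dpt (-0.98 ± 0.15). Tex11 rose by 1.15 ± 0.13, Fkbp5 by 0.74 ± 0.14 and the cell death gene Pmaip1 by 0.37 ± 0.09. As lists, cell cycle genes (median 0.71, adjusted p = 4.21e-10, or 0.608 with an estimated correlation), the neutrophil and monocyte chemokines and cytokines (median 0.62, adjusted p = 3.87e-05, or 0.608 with an estimated correlation) and natural killer cell markers (median 0.48, adjusted p = 9.44e-05, or 0.608 with an estimated correlation) were higher. Adjusted over the list alone 19 of 25, 8 of 16 and 6 of 10 of their genes rose, and over all genes 1 in each. Type 2 inflammation genes had a median of 0.28 (adjusted p = 0.00211, or 0.608 with an estimated correlation). Acute phase genes had a median of 0.28 (adjusted p = 0.0248, or 0.608 with an estimated correlation). Interferon-induced genes had a median of 0.38 (adjusted p = 0.0187, or 0.715 with an estimated correlation). Inflammasome and lysosomal genes had a median of 0.26 (adjusted p = 0.0158, or 0.608 with an estimated correlation). T cell markers had a median of 0.26 (adjusted p = 0.0282, or 0.608 with an estimated correlation). Endothelial markers had a median of -0.30 (adjusted p = 0.012, or 0.608 with an estimated correlation). Fibroblast markers had a median of -0.09 (adjusted p = 0.0158, or 0.157 with an estimated correlation).

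The 16 genes named for Graphite had adjusted p up to 0.050. The count of 187 genes became 3 without Ctrl 1, 24 without Ctrl 2, 79 without Ctrl 3, 35 without Graphite 13, 467 without Graphite 14, 486 without Graphite 15 and 72 without Graphite 16. Of the 16 named genes, Tex11 alone passed whichever sample was left out. The gene count was 39 with no array block, 0 with array as a fixed term and 0 with the other groups left out of the fit. It was 544 with slide as a term and 96 without the array of rCNT 4 and Graphite 16, an alternative chosen after seeing the data. Within slides 1 and 2 (2 samples against 1 and 2 against 2), 100% of the 187 genes, called on these same samples, had the same direction, and within slide 2 the test of the interferon-induced genes pointed lower at a median of 0.0645. Of the 10 lists called, 0 held with an estimated correlation and 1 by fry, and 6 were called without Graphite 15.

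After fullerene, the genes that changed included clock genes. Arntl fell by 2.15 ± 0.20 (SE, n = 4 against 3), while Per2 rose by 1.53 ± 0.21, the mitotic kinase Wee1, also under clock control, by 1.33 ± 0.14 and the clock repressor Nr1d2 by 1.08 ± 0.15. Of the clock genes, 5 of 15 (7 adjusted over the list alone) rose and 1 fell (median 0.34, adjusted p = 0.00131). Cholesterol synthesis genes were lower as a list, with the sterol sensor Insig1 at -0.72 ± 0.15, the 1 member that passed over all genes, and 6 of 14 lower adjusted over the list alone (median -0.22, adjusted p = 3.14e-06). Other genes that rose were the mitochondrial folate enzyme Mthfd1l by 1.18 ± 0.12, Tspan4 by 1.11 ± 0.13, Tex11 by 1.10 ± 0.14 and Fkbp5 by 1.05 ± 0.15. Spon2 fell by 1.96 ± 0.16, Sh3bp5 by 0.97 ± 0.18, the stress gene Ddit4 by 0.94 ± 0.19 and Serpina3c by 0.94 ± 0.16. Cell cycle genes had a median of 0.67 (adjusted p = 2.64e-12, or 0.306 with an estimated correlation), with 0 of 25 past the threshold over all genes and 14 adjusted over the list alone. The neutrophil and monocyte chemokines and cytokines had a median of 0.53 (adjusted p = 6.24e-06, or 0.306 with an estimated correlation). Type 2 inflammation genes had a median of 0.39 (adjusted p = 0.000416, or 0.481 with an estimated correlation), beside fullerene 21, whose Saa3 level of 12.4 lay above the 8.79 to 8.93 of the other 3 samples. Inflammasome and lysosomal genes had a median of 0.23 (adjusted p = 0.0279, or 0.481 with an estimated correlation). Metal response genes had a median of 0.13 (adjusted p = 0.0497, or 0.481 with an estimated correlation). Alveolar macrophage markers had a median of 0.24 (adjusted p = 0.0398, or 0.306 with an estimated correlation). Fat markers had a median of -0.44 (adjusted p = 0.000856, or 0.306 with an estimated correlation). Alveolar type 1 cell markers had a median of -0.13 (adjusted p = 0.0398, or 0.481 with an estimated correlation). Endothelial markers had a median of -0.19 (adjusted p = 0.0497, or 0.569 with an estimated correlation). Markers of smooth muscle and pericytes had a median of -0.18 (adjusted p = 0.0497, or 0.569 with an estimated correlation). Those of red blood cells had a median of -0.31 (adjusted p = 0.0497, or 0.499 with an estimated correlation).

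The 13 genes named for fullerene had adjusted p from 1.9e-06 to 0.047. The count of 43 genes became 18 without fullerene 21, 26 without fullerene 22, 19 without fullerene 23, 27 without fullerene 24, 15 without Ctrl 1 and 11 without Ctrl 2. Of the 13 named genes 9, Arntl, Per2, Nr1d2, Wee1 and Spon2 among them, passed whichever sample was left out. The gene count was 1 with array as a fixed term and 13 with the other groups left out of the fit. Within slides 1 and 2 (1 sample against 1 and 1 against 2), 100% of the 43 genes had the same direction. Of the 13 lists called, 2 held with an estimated correlation and 2 by fry, and the count was 7 without fullerene 21, 6 without fullerene 22 and 7 without Ctrl 1. Within slide 1 the list tests turned for cell cycle (median -0.179), inflammasome and lysosomal (0.0698), alveolar macrophage (0.00918), alveolar type 1 (0.102), smooth muscle (0.0822) and fat (0.207) genes. Within slide 2 they turned for alveolar type 1 (0.341), endothelial (0.242), smooth muscle (0.494) and red blood cell (0.5) genes.

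**Figure D3:**
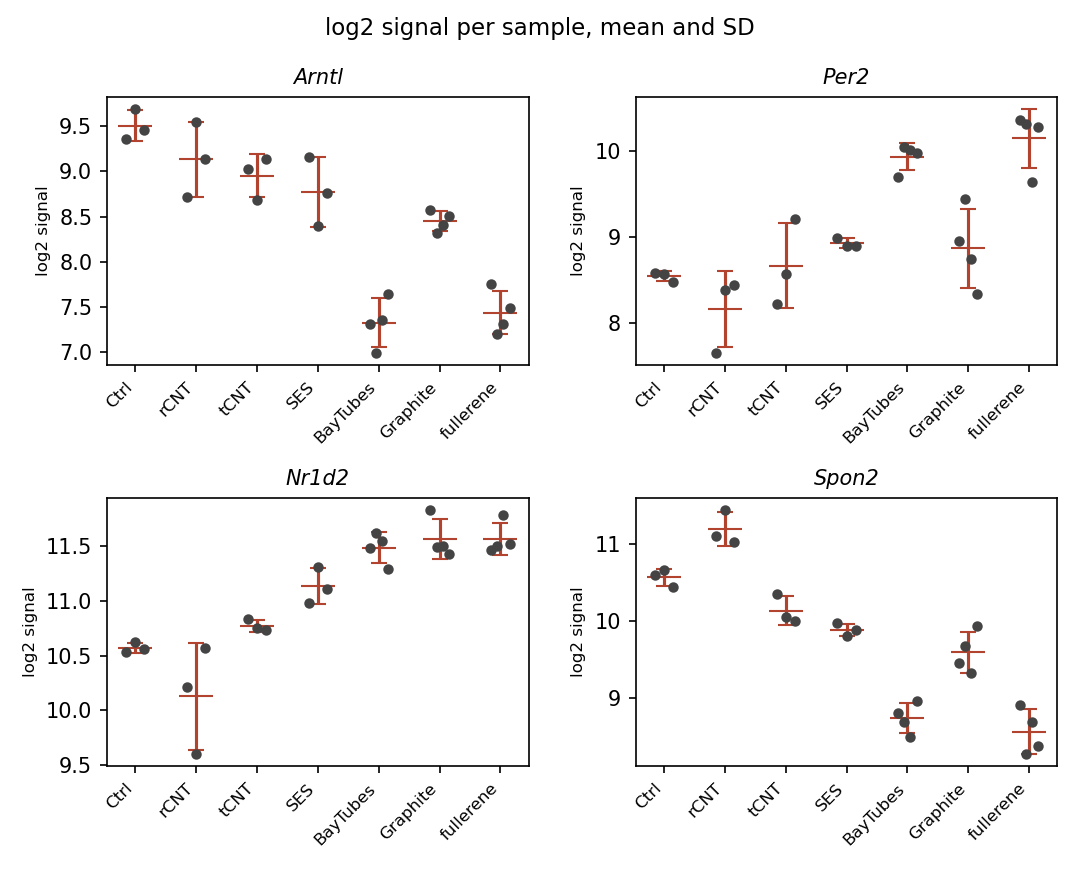
Log2 signal of clock genes in each sample (vertical axes: log2 signal; horizontal axes: group). Points are samples and bars are group means with SD. The Arntl mean is 9.51 in Ctrl, 7.32 in BayTubes and 7.44 in fullerene.

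**Figure D4:**
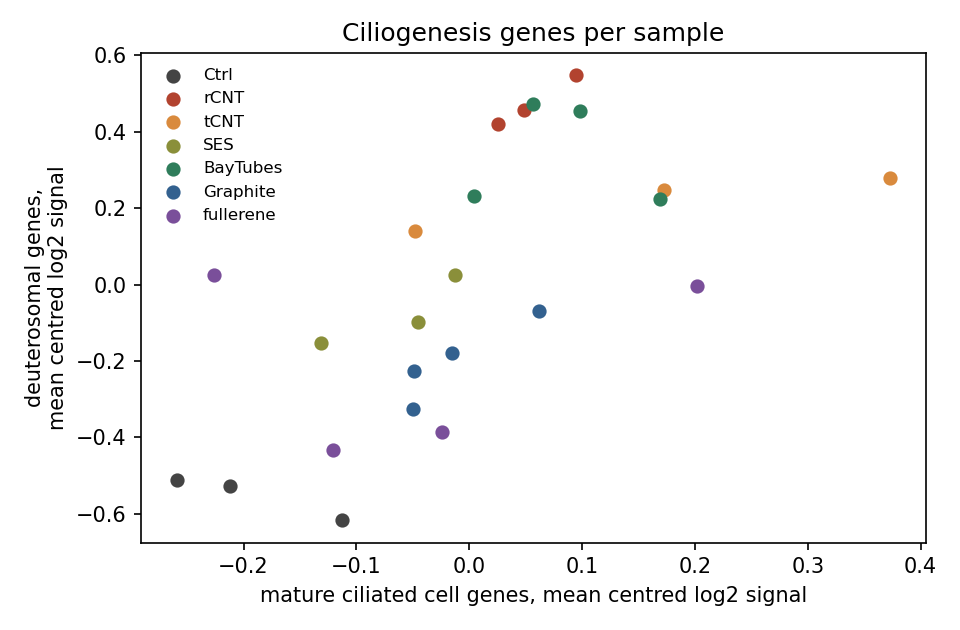
Mean centred log2 signal per sample of 9 genes that deuterosomal cells, the precursors of ciliated cells, express (vertical axis) and of 12 genes of mature ciliated cells (horizontal axis). Points are samples, and all samples of the 6 materials lie above the 3 Ctrl samples on the vertical axis.

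**Figure D5:**
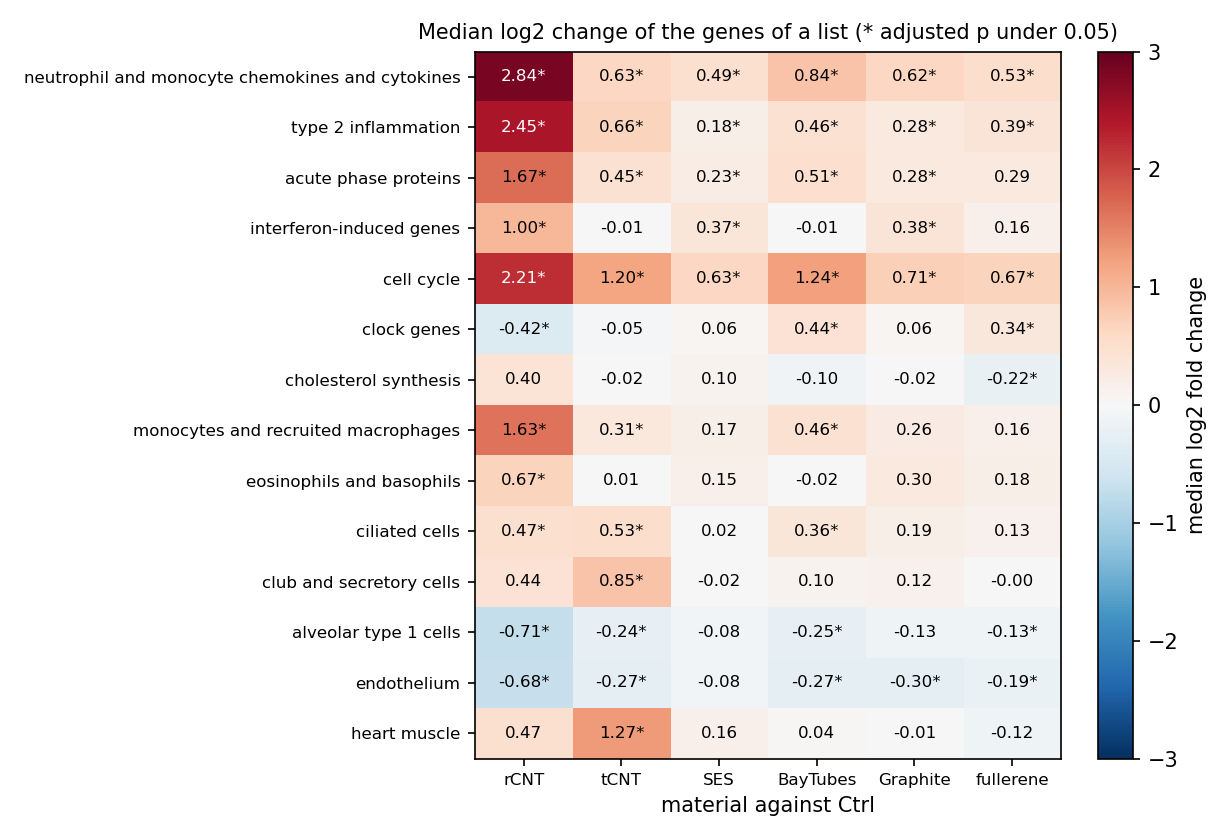
Median log2 change of the genes of 14 lists (vertical axis) in each material against Ctrl (horizontal axis), with a star at an adjusted p under 0.05 by camera. Cell cycle genes have medians of 2.21 after rCNT and 1.24 after BayTubes.

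The question of how distinct the gene sets are was taken up by counting genes called in several comparisons. At least 1 comparison against Ctrl called 3757 genes, of which 519 were called in the same direction in 2 or more (368 higher, 151 lower) and 148 in 3 or more. After rCNT, tCNT and BayTubes together 102 genes were higher, and 115 of the 117 genes called after tCNT were called in the same direction after rCNT. For BayTubes this held for 411 of 526 genes, with 10 opposite, for Graphite for 92 of 187, with 7 opposite, and for fullerene for 18 of 43, with 3 opposite. Genes called in 1 comparison alone numbered 3121 for rCNT, 55 for BayTubes, 49 for Graphite, 3 for fullerene and 1 for tCNT, which does not show that the other materials left them unchanged.

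Shared calls are given beside the number for independent lists, which is not the value without change, because the pairs share the 3 Ctrl samples. Samples of different materials also shared arrays, such as rCNT 4 and Graphite 16 (residual correlation 0.827) and tCNT 7 and BayTubes 17 (0.498). In 50 simulated sets of unchanged groups 0 genes were called in 2 or more comparisons, which is no reference for groups with real changes. For rCNT and tCNT 111 genes were shared higher against 14.0 for independent lists and 4 lower against 0.376. For rCNT and BayTubes they were 327 against 44.1 and 84 against 15.9. For rCNT and Graphite they were 60 against 11.1 and 32 against 9.12. For rCNT and fullerene they were 11 against 3.09 and 7 against 1.69. tCNT and BayTubes shared 103 higher against 2.44 and 3 lower against 0.0409. tCNT and Graphite shared 24 against 0.615 and 0 lower against 0.0235, and tCNT and fullerene 4 against 0.171 and 0 lower against 0.00436. BayTubes and Graphite shared 47 against 1.94 and 45 against 0.992. BayTubes and fullerene shared 22 against 0.540 and 16 against 0.184, and Graphite and fullerene 12 against 0.136 and 6 against 0.106. Across genes, which are not independent replicates, the covariance of the log2 changes of rCNT and tCNT was 0.1 against 0.0260 in simulated unchanged groups, and the correlation 0.695 against 0.515. For tCNT and BayTubes the covariance was 0.0531 against 0.0230 and the correlation 0.795 against 0.555. The covariance exceeded the simulated one in all 15 pairs, while the correlation lay below the simulated one for rCNT with SES (0.455 against 0.488), Graphite (0.619 against 0.63) and fullerene (0.546 against 0.6). For rCNT and SES the covariance was 0.0499 against 0.0241. The 3 controls cannot be split between comparisons, so the part of the excess that comes from the shared controls was not separated. Nor was the part that comes from shared arrays. The count of 519 shared genes became 235 without Ctrl 3, 286 without Ctrl 1, 209 without Ctrl 2 and 265 without BayTubes 20, and it was 242 with no array block and 34 with array as a fixed term.

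Whether the 2 nanotubes rCNT and tCNT act differently was tested directly. Ccl24 was higher after rCNT than after tCNT by 5.58 ± 0.48 (SE, n = 3 against 3), Ccl7 by 4.05 ± 0.33, Cxcl5 by 3.98 ± 0.35, Arg1 by 3.98 ± 0.49 and Retnlb by 3.71 ± 0.32. Higher too were Saa3 by 3.71 ± 0.59, Fbp1, an enzyme of sugar metabolism, by 3.70 ± 0.51, Ccl2 by 3.59 ± 0.37 and Prg2 by 2.58 ± 0.33. The interferon-induced Rsad2 and Mx2 were higher by 1.78 ± 0.22 and 1.29 ± 0.15, while Pon1 (-1.52 ± 0.24), Fabp1 (-1.56 ± 0.26) and Txnip (-2.05 ± 0.57) were lower. The neutrophil and monocyte chemokines and cytokines were higher in 15 of 16 (15 adjusted over the list alone; median 2.09, adjusted p = 2.35e-37). Type 2 genes were higher in 17 of 27 (21 adjusted over the list alone; median 1.53, adjusted p = 4.86e-33), and acute phase genes in 10 of 14 (11 adjusted over the list alone; median 1.39, adjusted p = 1.72e-16). Interferon-induced genes were higher in 14 of 22 (19 adjusted over the list alone; median 1.01, adjusted p = 1.69e-21). Cell cycle genes were higher in 20 of 25 (22 adjusted over the list alone; median 1.08, adjusted p = 2.25e-15, or 0.107 with an estimated correlation), and dendritic cell markers in 3 of 12 (6 adjusted over the list alone; median 0.36, adjusted p = 0.000138). Clock genes were lower in 4 of 15 (7 adjusted over the list alone; median -0.19, adjusted p = 0.00782). Heart muscle markers had a median of -0.85 (adjusted p = 0.0154, or 0.48 with an estimated correlation). The other 12 lists called had medians between -0.55 and 1.10 and lost the call with an estimated correlation, with adjusted p from 0.0547 to 0.427, and fry called 17 of the 20.

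In all, 1459 genes differed between rCNT and tCNT in limma, 942 higher and 517 lower, and 13 of the 14 genes named, all but Txnip, passed whichever sample was left out. The count became 463 without tCNT 7 and 873 without tCNT 9, and the 20 lists became 12 without rCNT 5. The gene count was 12 with array as a fixed term, 55 with the other groups left out of the fit and 3275 within slide 1, where 99.9% of the 1459 genes had the same direction (1 sample against 2).

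Each material was also set against the mean of the other 5, a comparison that uses no Ctrl sample and in which, for the 5 materials other than rCNT, this mean includes rCNT. rCNT stood apart with 4334 genes (2284 higher, 2050 lower). Ccl24 was higher by 5.75 ± 0.36 (SE, n = 3 against 18), Cxcl5 by 4.23 ± 0.27, Arg1 by 4.22 ± 0.37, Fbp1 by 4.09 ± 0.38 and Ccl7 by 4.04 ± 0.25. Retnlb was higher by 3.83 ± 0.24, Saa1 by 3.42 ± 0.30, the eosinophil receptor Ccr3 by 1.71 ± 0.22 and Foxj1 by 1.33 ± 0.14, while Pon1 (-1.80 ± 0.18) and Fabp1 (-1.87 ± 0.20) were lower. All 11 passed whichever sample was left out. Clock genes were lower in 9 of 15 (9 adjusted over the list alone; median -0.71, adjusted p = 3.71e-05). Of the 17 lists called, 8 held with an estimated correlation and fry called 17. The count was 5319 with slide as a term and 936 with array as a fixed term.

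Against the other 5 materials, tCNT had 0 genes past the threshold in limma, and 10 without Graphite 15. At an unadjusted p under 0.05 there were 666, fewer than unchanged genes alone would be expected to give. With a spread estimate shared by all groups, this does not show that tCNT acted like the other materials. The values were 0.66 ± 0.11 for Tnni3k (SE, n = 3 against 18, adjusted p = 0.16), -0.56 ± 0.10 for Ifit3b (adjusted p = 0.17) and 0.77 ± 0.16 for Arntl (adjusted p = 0.28). Ciliated cell markers were higher as a list (median 0.20, adjusted p = 3.71e-09), as were club and secretory cell markers (median 0.54, adjusted p = 6.31e-09). Heart muscle markers were higher (median 1.13, adjusted p = 6.89e-25), of which 0 of 12 passed over all genes and 11 adjusted over the list alone. Interferon-induced genes were lower (median -0.36, adjusted p = 4.5e-15). Of the 14 lists called, 6 held with an estimated correlation and 0 by fry.

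SES differed from the other 5 materials in 1 gene, Lrrc43 at -0.50 ± 0.07 (SE, n = 3 against 18, adjusted p = 0.022), with 1499 at an unadjusted p under 0.05. Spag11b (1.01 ± 0.17), Cxcl17 (-0.48 ± 0.09) and Ccl7 (-1.33 ± 0.24) had adjusted p of 0.064. Some lists were lower after SES than in the mean of the other 5, which includes rCNT. Among them were type 2 genes (median -0.74, adjusted p = 1.06e-18) and the neutrophil and monocyte chemokines and cytokines (median -0.68, adjusted p = 5.08e-16). Acute phase genes (median -0.43, adjusted p = 1.02e-08) and ciliated cell markers (median -0.20, adjusted p = 6.17e-06) were lower too, and these 4 lists also passed by fry, out of 16 called by camera. Against Ctrl, camera called the type 2, chemokine and acute phase lists higher after SES, which did not hold with an estimated correlation. The count of 1 became 0 without SES 10, SES 11, SES 12, tCNT 8, rCNT 5 or fullerene 22. It was 36 without rCNT 4, 22 without fullerene 21, 10 without BayTubes 17, 6 without BayTubes 19, 5 without Graphite 13, 3 without BayTubes 18 or tCNT 9 and 2 without BayTubes 20, Graphite 14 or fullerene 24.

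BayTubes differed from the other 5 materials in 21 genes (7 higher, 14 lower). Per2 (1.04 ± 0.15, SE, n = 4 against 17), Dbp (0.82 ± 0.15) and Hlf (0.66 ± 0.11), outputs or parts of the clock, and Foxn4 (0.68 ± 0.13), which acts in the making of ciliated cells, were higher. Arntl (-1.24 ± 0.14), Spon2 (-1.15 ± 0.11) and the interferon-induced Rsad2 (-0.88 ± 0.15), Cmpk2 (-0.60 ± 0.12) and Mx2 (-0.53 ± 0.10) were lower than the mean of the other 5, which includes rCNT, and none of these 3 was among the 48 genes that differed without rCNT. Clock genes were higher in 5 of 15 (10 adjusted over the list alone; median 0.44, adjusted p = 6.79e-12), and interferon-induced genes lower in 2 of 22 (8 adjusted over the list alone; median -0.38, adjusted p = 7.29e-15, or 0.0955 with an estimated correlation). For Spon2 and the clock genes named, fullerene lay as far out as BayTubes or nearly so. Means after BayTubes and fullerene were 9.93 and 10.14 for Per2, 14.7 and 14.75 for Dbp and 10.84 and 10.88 for Hlf. They were 7.32 and 7.44 for Arntl and 8.74 and 8.57 for Spon2. Mean Foxn4 was 9.71 after rCNT and 9.54 after BayTubes. Between BayTubes and fullerene 6 genes differed. Of the 9 genes named, Arntl and Spon2 passed whichever sample was left out. The count of 21 became 4 without BayTubes 17, 2 without BayTubes 18, 3 without BayTubes 19 and 10 without BayTubes 20. It was 3 without SES 12, 12 without tCNT 8, 12 without tCNT 9, 13 without rCNT 5, 13 without fullerene 22 and 13 without fullerene 23. It was 13 with slide as a term and 0 with array as a fixed term.

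Graphite differed from the other 5 materials in 205 genes (119 higher, 86 lower), of which 33 changed by at least 1.5-fold. Genes lower than the mean of the other 5, which includes rCNT, were Slc26a4 (-1.28 ± 0.29, SE, n = 4 against 17), Agr2 (-1.10 ± 0.23), Retnla (-1.19 ± 0.28) and Foxj1 (-0.73 ± 0.13). Also lower were Cxcl5 (-1.11 ± 0.23), Il33 (-0.65 ± 0.14), Il6 (-0.71 ± 0.15) and the surfactant protein gene Sftpd (-0.72 ± 0.16). Higher were the endothelial gene Esm1 (0.74 ± 0.16), the kinase Prkca (0.71 ± 0.10), Klra2 (0.71 ± 0.16), Il18 (0.56 ± 0.12) and Kit (0.47 ± 0.10). Here too the mean of the other 5 includes rCNT. Mean Esm1 was 12.51 after Graphite, 12.21 in Ctrl and 10.61 after rCNT, and mean Il18 was 10.22, 9.76 and 8.87. Type 2 genes were lower in 4 of 27 (18 adjusted over the list alone; median -0.63, adjusted p = 1.94e-10, or 0.262 with an estimated correlation). Natural killer cell markers had a median of 0.33 (adjusted p = 4.17e-06, or 0.262 with an estimated correlation). Of the 13 genes named, Prkca alone passed whichever sample was left out. The count of 205 became 18 without Graphite 13, 46 without Graphite 14, 406 without Graphite 15 and 19 without Graphite 16. It was 440 without rCNT 4, 130 without tCNT 8, 78 without SES 12, 122 without BayTubes 20 and 454 without fullerene 23. It was 84 with slide as a term and 0 with array as a fixed term.

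Fullerene differed from the other 5 materials in 124 genes (56 higher, 68 lower). Per2 (1.15 ± 0.14, SE, n = 4 against 17), Per1 (0.89 ± 0.10) and Dbp (0.89 ± 0.14) were higher and Arntl (-1.19 ± 0.13) lower, and clock genes were higher in 8 of 15 (9 adjusted over the list alone; median 0.54, adjusted p = 1.56e-11). Gsta3 was higher by 0.69 ± 0.15 than this mean, which includes rCNT. Mean Gsta3 was 14.42 after fullerene, 14.16 in Ctrl, 12.48 after rCNT and 13.74 to 14.1 after the rest. Spon2 was lower at -1.33 ± 0.11. BayTubes lay near fullerene for Spon2 (8.74 and 8.57), Per2 (9.93 and 10.14) and Arntl (7.32 and 7.44). Cholesterol synthesis genes were lower in 3 of 14 (11 adjusted over the list alone), with Dhcr7 at -0.51 ± 0.09 and Fdps at -0.42 ± 0.08 (median -0.33, adjusted p = 6.48e-17). Genes lower than the mean of the other 5 materials, which includes rCNT, were Agr2 (-1.28 ± 0.22), Ccl2 (-1.19 ± 0.24), Ccl17 (-1.05 ± 0.19), Cxcl1 (-1.03 ± 0.20), Serpina3n (-0.89 ± 0.16), Lcn2 (-0.87 ± 0.19) and Ear6 (-0.84 ± 0.13). Acute phase genes were lower in 4 of 14 (12 adjusted over the list alone; median -0.51, adjusted p = 6.48e-17). Type 2 genes were lower in 3 of 27 (14 adjusted over the list alone; median -0.61, adjusted p = 9.82e-17) and the neutrophil and monocyte chemokines and cytokines in 4 of 16 (10 adjusted over the list alone; median -0.58, adjusted p = 1.09e-12). Of the 15 genes named, 6 passed whichever sample was left out. The count of 124 became 59 without fullerene 22, 33 without fullerene 23, 23 without fullerene 24, 64 without SES 10, 198 without rCNT 4, 73 without tCNT 9 and 238 without Graphite 13. It was 69 with slide as a term and 2 with array as a fixed term.

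Across the 6 materials, an F test in limma found 2717 genes that differed, and 2486 of them also differed between rCNT and the other 5. Without rCNT in the test, 48 genes differed among the 5 materials, with 1408 at an unadjusted p under 0.05. By the smallest adjusted p, chosen after the values were seen, these were Spon2 (5.67e-06), Arntl (1.78e-05), Tspan4 (0.00016), Per1 (0.000354), Per2 (0.000417) and Mthfd1l (0.000423). Between pairs of materials, those with rCNT differed in 1459 to 4311 genes and the 10 other pairs in 0 to 24. The pair with 0 was SES and Graphite, with 1023 genes at an unadjusted p under 0.05 in limma. The F test count was 429 with array as a fixed term.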

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

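The tests of the 3 patterns weighed here, and the values on Graphite, were chosen only after the results were seen; the counts over other splits of the samples were planned. The deuterosomal genes were listed after Deup1, Ccno and Foxn4 had been seen, and the tests of time of day, airway tissue, low controls, dividing cells and exchanged labels replaced earlier ones whose results were known.

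In groups of 4 samples, 24 of 423 values tested lay far from the 3 others by Dixon's test, which chance gives in about 1 in 20 groups. In fullerene 21 these were Saa3 (12.4, others 8.79 to 8.93), Saa1 (10.3, others 7.9 to 8.24), Slc26a4 (10.2, others 8.8 to 9), Ccl2 (9.55, others 7.71 to 7.95), Arg1 (9.06, others 6.84 to 7.16), Cxcl1 (7.52, others 6.58 to 6.66) and Cxcl5 (7.37, others 5.8 to 6.01). In Graphite 13 they were Cxcl5 (7.06, others 5.93 to 5.99), Foxp3 (6.99, others 6.16 to 6.24), Ykt6 (8.61, others 9.05 to 9.13) and Nr1d2 (11.8, others 11.4 to 11.5), in Graphite 16 Hipk2 (8.71, others 9.32 to 9.38) and in Graphite 14 the mesothelium score (0.125, others -0.108 to -0.0899). In BayTubes 17 they were Clca1 (12.5, others 10.3 to 10.6), Ramp2 (15.4, others 15.7), Cyp2f2 (16.2, others 16.4 to 16.5) and the alveolar macrophage score (0.198, others -0.0337 to 0.00236). In BayTubes 20 they were Wee1 (9.53, others 9.09 to 9.13), Fbp1 (7.4, others 7.09 to 7.11), Lrrc43 (8.37, others 8.41 to 8.42) and Il33 (12.7, others 12.1 to 12.2). The remaining values were Inmt in fullerene 24 (16.8, others 16.5), Per2 in fullerene 23 (9.64, others 10.3 to 10.4) and Col13a1 in fullerene 22 (7.27, others 6.63 to 6.74).

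Spots without a gene name, of which 16650 were tested, also passed the threshold. Against Ctrl these were 928 after rCNT, 66 after BayTubes, 16 after Graphite, 5 after tCNT and 2 after fullerene. Against the other 5 materials they were 1324 for rCNT, 39 for Graphite, 18 for fullerene and 1 for BayTubes. Between rCNT and tCNT there were 110, and 613 in the F test.

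Clock genes shifted after BayTubes and fullerene. Genes that peak with Arntl, the early arm, changed by -0.566 ± 0.0967 (SE, n = 4 against 3) and -0.491 ± 0.109, mostly through Arntl itself, and the late arm by 0.632 ± 0.104 and 0.623 ± 0.117, while the 4 genes of each arm not named in the report changed by -0.16 ± 0.0819 and -0.0759 ± 0.0922 (early, with Cry1 at 0.507 and 0.82) and by 0.473 ± 0.142 and 0.263 ± 0.16 (late, with Nr1d1 at -0.119 after fullerene). A slide difference is argued against, since Arntl stayed at -2.15 and -2.27 with slide as a term. For the fall of Arntl, so is the size of the inflammatory response, since Arntl was higher after rCNT, with the most changed genes, by at least 1.74 ± 0.187. After rCNT the late arm moved the other way, by -0.705 ± 0.126, and late minus early by -0.852 ± 0.231 (SE, n = 3 against 3). Another link of inflammation to the clock thus stays open. After Graphite late minus early was 0.496 ± 0.204 (n = 4 against 3), so the shift was not limited to BayTubes and fullerene. Groups collected at different times of day cannot be told apart. On the genes not named in the report, the late minus the early arm was 0.633 ± 0.208 after BayTubes but 0.339 ± 0.234 after fullerene. The labels number the samples by group, in the order Ctrl, rCNT, tCNT, SES, Graphite, BayTubes and fullerene. Mean Arntl in that order was 9.51, 9.13, 8.95, 8.77, 8.45, 7.32 and 7.44, a fall along almost all groups. Per2, at 8.54, 8.16, 8.67, 8.93, 8.87, 9.93 and 10.14, followed the order less closely. The labels do not say whether the numbers follow collection, and they give no collection times. An effect of the materials on the clock was not tested and stays open.

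In fullerene 21, 23 genes were examined that were higher after rCNT by over 2.5 log2 units against Ctrl and also against tCNT. Of these, 23 of 23 were above the mean of the other fullerene samples, by a median of 1.11. The next largest departure of a sample outside rCNT was 0.601. A sample of Ctrl, rCNT, tCNT or SES under its label is argued against: on the 100 genes that separate each from the other fullerene samples, fullerene 21 lay at least 70.6% of the way to fullerene, and samples of these groups, left out in turn, at most 46.5%. A Graphite or BayTubes sample cannot be told apart, because fullerene 21 lay at 77.8% and 41.2% where real samples overlapped (Graphite to 64.4% and fullerene from 41.7%, BayTubes to 50.3% and fullerene from 40.1%), though single values lay nearer fullerene: Arntl at 7.75, against 7.2 to 7.48 in the other fullerene samples and at least 8.32 in Graphite, and the deuterosomal score at 0.0249, against -0.434 to -0.00458 and at least 0.224 in BayTubes, while this score minus that of mature ciliated cells, at 0.251, lay within BayTubes (0.0552 to 0.416). Signal of rCNT 5 on the same array cannot be told apart from other causes. Of the 23 genes, 3 lay further than 2 residual SDs from a common share of 9.4% of the rCNT 5 signal. These SDs include the scatter of the rCNT samples and of fullerene 21 itself, so this count is a weak test. The criterion was written after the shares had been seen. They ran from 1.45% for Ccl24 (predicted 9.74, measured 7.62) to 76.4% for Acod1. A response of the mice in this pool stays open and was not tested.

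Deuterosomal genes, which precursors of ciliated cells express, were higher by 0.959 ± 0.107 after rCNT (SE, n = 3 against 3), 0.77 ± 0.106 after tCNT and 0.894 ± 0.0876 after BayTubes, and the 6 outside those seen first by 0.548 ± 0.0887, 0.451 ± 0.0878 and 0.491 ± 0.0727, although Mcidas was at -0.599, -0.243 and -0.0809. More airway tissue with all its cell types alike is argued against as the whole cause, since these 6 genes rose more than club cell genes by at least 0.461 ± 0.143. It is not excluded beside more dividing cells, which could open the same gap. More ciliated airway lining cannot be told apart, because these 6 genes exceeded genes of mature ciliated cells by 0.255 ± 0.102 after rCNT and 0.173 ± 0.0837 after BayTubes but by 0.0618 ± 0.101 after tCNT. Low controls are argued against as the whole cause, since 70.6% of the variance of these 6 genes over the 21 samples of the 6 materials lay between materials (permutation p = 0.002), but a rise of at least 0.164 ± 0.0781 in all 6 materials leaves a common part open. The permutation treats samples as exchangeable, although samples that shared an array resembled each other. More dividing cells cannot be told apart, because only 3 measured genes, Hes6, Gmnc and Mcidas, with a smallest mean change of 0.121 ± 0.0978, lie outside those seen first and those of dividing cells. Foxj1 was left out of the genes of mature ciliated cells. Its mean was 11.32 after rCNT, 10.84 after tCNT and 10.07 after BayTubes, against 10.28 in Ctrl. After SES the mean of the 9 deuterosomal genes rose by 0.451 ± 0.104. It exceeded that of mature ciliated cells by 0.368 ± 0.107, beside 0.38 ± 0.109 after tCNT, so the rise was not limited to rCNT, tCNT and BayTubes. Early ciliated cell formation after rCNT, tCNT and BayTubes may be a further explanation and was not tested.

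Other splits of the same samples were counted for each comparison. For BayTubes, Graphite and fullerene against Ctrl, 1 of 35 splits, the real one, gave as many genes: 526 against a highest other count of 335, 187 against 154 and 43 against 1. The splits treat samples as exchangeable, but samples that shared an array resembled each other, so these shares do not exclude chance. With array as a fixed term the real counts were 61, 0 and 1. The splits with 335 and 154 genes put BayTubes 19 or Graphite 15 together with all 3 Ctrl samples. For rCNT, tCNT and SES against Ctrl and for rCNT against tCNT, 10 splits are too few for a share under 0.05, with real counts of 3598, 117, 0 and 1459 and highest other counts of 0, 0, 0 and 1. As many genes were given by 1, 1, 10 and 1 of them.

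Against the other 5 materials, with 100 splits each, 1 gave as many genes as the 4334 of rCNT (highest other 2334), 4 as many as the 21 of BayTubes (2247), 3 as many as the 205 of Graphite (630) and 2 as many as the 124 of fullerene (780). These splits too treat samples as exchangeable, so these shares do not exclude chance. With array as a fixed term, which the splits leave out, the real counts were 936, 0, 0 and 2. For SES 12 of 100 gave at least its 1 gene (highest other 1542), so chance cannot be excluded. For tCNT 100 of 100 gave at least its 0 genes (2281), which any data would give and which decides nothing. Splits with many times the real count point to a structure of the samples. In the F test 1 of 100 splits gave as many as 2717 genes (highest other 868), under the same limit, and with array as a fixed term 429 genes differed.

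The 187 genes called after Graphite had a median change of 0.683, and the other 5 materials lay on the same side of Ctrl in 99.5% of them, at 0.392. This was 57.5% of the Graphite change, against 60.2% in simulated unchanged groups (highest 66.1%). With slide as a term the median was 0.699, and without the array of rCNT 4 and Graphite 16 it was 0.677 (quartiles 0.536 and 0.846), with 79 of the 187 genes called.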

How the results depend on the processing

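Leaving out the array of rCNT 4 and Graphite 16 was chosen after seeing the data; the other alternatives were planned. Unless a sentence gives the reason, the cause was not tested.

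With 1 sample left out at a time, the genes changed against Ctrl numbered 2445 to 3633 for rCNT, 0 to 327 for tCNT, 0 to 0 for SES, 241 to 558 for BayTubes, 3 to 486 for Graphite, 11 to 33 for fullerene. Against the other 5 materials they were 3083 to 5152 for rCNT, 0 to 10 for tCNT, 0 to 36 for SES, 2 to 31 for BayTubes, 18 to 454 for Graphite, 23 to 238 for fullerene. The ranges were 463 to 2153 between rCNT and tCNT, 2064 to 3375 in the F test and 209 to 629 for shared genes. The lists called against Ctrl were 16 to 23 for rCNT, 11 to 16 for tCNT, 5 to 13 for SES, 11 to 17 for BayTubes, 6 to 12 for Graphite, 6 to 14 for fullerene, and 12 to 21 between rCNT and tCNT.

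With array as a fixed term, which leaves fewer degrees of freedom, the counts against Ctrl were 1074 for rCNT, 0 for tCNT, 61 for BayTubes, 0 for Graphite and 1 for fullerene. Against the other 5 they were 936 for rCNT, 0 for SES, BayTubes and Graphite and 2 for fullerene. There were 12 genes between rCNT and tCNT, 429 in the F test, 34 shared, and 4 lists for SES and 5 for Graphite. With no array block they were 240 for BayTubes and 39 for Graphite against Ctrl, 0 for SES, 6 for BayTubes and 62 for fullerene against the other 5, 242 shared, and 13 lists for SES. With only the groups compared in the fit, which leaves fewer samples, the counts were 1009, 51, 2, 79, 0 and 13 for rCNT, tCNT, SES, BayTubes, Graphite and fullerene, 8 for BayTubes and 11 for Graphite against the other 5, 55 between rCNT and tCNT, and 15 lists for SES.

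With slide as a term, the counts were 544 for Graphite against Ctrl, and 3, 13, 84 and 69 for SES, BayTubes, Graphite and fullerene against the other 5. Within slide 1 they were 0 for tCNT, 5 for BayTubes, 6 for Graphite, 0 for fullerene, 3275 between rCNT and tCNT and 8 shared, with 8, 11 and 4 lists for rCNT, SES and fullerene and 9 between rCNT and tCNT. Within slide 2 they were 2380 for rCNT, 8 for SES, 1986 for BayTubes, 501 for Graphite and 786 for fullerene, with 11, 5 and 5 lists for SES, Graphite and fullerene. On slide 3 rCNT and tCNT could not be compared, with no residual degrees of freedom.

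A change of at least 1.5-fold was kept by 2145 genes for rCNT and 327 for BayTubes against Ctrl, by 1511, 0, 33 and 45 for rCNT, SES, Graphite and fullerene against the other 5, and by 866 between rCNT and tCNT. A filter at the 60th percentile gave 11 genes for SES against the other 5 and 7 lists for fullerene, and no filter 13 genes for BayTubes against the other 5. The mean of the spots of a gene gave 0 for SES and 11 for BayTubes against the other 5, and 8 lists for fullerene. No dye term gave 131 for Graphite and trended, robust variances 0 for SES, both against the other 5. Without the array of rCNT 4 and Graphite 16 the counts were 96 for Graphite against Ctrl, and 19 for SES and 32 for BayTubes against the other 5. With an estimated correlation 6, 5, 0, 4, 0 and 2 lists held for rCNT, tCNT, SES, BayTubes, Graphite and fullerene, and 6 between rCNT and tCNT. fry called 6, 0, 1 and 2 for tCNT, SES, Graphite and fullerene.

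The direction was reversed for 20 results, all within 1 slide. Within slide 2 these were red blood cell markers after rCNT (0.467), alveolar macrophage (-0.0948), alveolar type 1 (0.3), endothelial (0.134) and red blood cell markers (0.599) after BayTubes, interferon-induced genes after Graphite (0.0645, where the test turned), and alveolar type 1 (0.341), endothelial (0.242), smooth muscle (0.494) and red blood cell markers (0.5) after fullerene. The genes were Ramp2 (0.0791) and Abca3 (0.0791) after rCNT and Rsph1 (-0.0892) and Dpt (0.0487) after BayTubes. Within slide 1 they were, after fullerene, cell cycle (-0.179), alveolar type 1 (0.102), smooth muscle (0.0822) and fat genes (0.207). There the inflammasome (0.0698) and alveolar macrophage (0.00918) genes kept the sign of their median, and only the test turned.

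Counting each gene named once per comparison, all 192 kept direction and side of the threshold with quantile normalization, 191 with scaling to the 75th percentile, 168 with slide as a term, 162 with no array block, 117 with only the groups compared and 81 with array as a fixed term. Quantile normalization moved no value by more than 0.00896. The values hold no background signal, so what signal over background limits was not measured.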

Other observations

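The lists and their tests were planned. In none of the 6 comparisons against Ctrl did camera call the lists of DNA damage and p53 targets, heat shock or endoplasmic reticulum stress, nor the markers of neutrophils, mast cells or alveolar type 2 cells. In rCNT fry did call genes of endoplasmic reticulum stress higher and alveolar type 2 markers lower (adjusted p = 0.0449 each). A list that was not called can hold changed genes: after rCNT 4 of the 12 neutrophil markers were higher and 1 lower, with a mean score of 0.88 ± 0.19 (SD, n = 3) against 0.00 ± 0.07 in Ctrl.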
